A study of Mus musculus with 20 samples.

How the data were processed

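Passage 2 embryonic fibroblasts of OG2 mice were infected with retroviruses carrying the reprogramming factors and grown in iCD1 medium, with a control shRNA against luciferase or an shRNA against Ddx10, per the labels' protocols. Total RNA was taken with TRIzol at days 0, 1, 3, 5 and 7, and messenger RNA libraries were sequenced in paired ends on an Illumina HiSeq instrument, per the labels. Each of the 10 groups of arm and day holds 2 libraries. The series text calls the replicates biological, but no label says whether they are separate cultures, so the p-values measure only the spread between these samples. No label gives a batch or a date.

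The values are signal of the kind deposited by the authors as normalized read counts per gene, in 1 table of 15757 genes and 20 columns. Trim Galore 0.4.4, STAR 2.5.2a, RSEM 1.2.22, DESeq2 1.22.0 and the mm10 genome are named by the authors, per the submitters' processing notes, without the order or the role of each. The normalization step, the annotation and the gene filter are not stated. In the table, each column's low values cluster at 1 step, but only 43.2 to 60.9% of the values up to 20 steps lie within 0.1 of a whole number of steps. Whole reads could therefore not be recovered, and the tests for read counts planned before the data were examined were replaced by limma on log values. The step and the column sum put the depth at about 12.0 M to 23.7 M reads per library. Every gene reaches at least 7.61 in some library, so genes with low values had been left out before deposit. Between 75 (knockdown replicate 2 of day 5) and 739 (control replicate 1 of day 0) genes were at 0, the top 10 genes held 3.93 to 7.70% of the sums, and 0 pairs of columns were identical. Of the gene identifiers, 15665 (99.4%) were found in the GENCODE names and 92 were not, and 24 symbols that were blank or turned into dates were restored from their identifiers.

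Values were transformed to log2(value + 1). The filter, set before the data were examined, asked for at least 1 in at least 2 libraries and removed 0 genes. All 20 libraries went into 1 limma fit with 10 group means (empirical Bayes with trend and robust settings; residual degrees of freedom 10, median prior degrees of freedom 5.35), and p-values were adjusted over 15757 genes by the method of Benjamini and Hochberg with a threshold of 0.05. The comparisons were knockdown against control at each day and as the mean of all days, each later day against day 0 in the control, day 7 against day 0 in the knockdown, and the difference between the arms in that change. The median standard error of a log2 fold change was 0.156 for a single day, 0.07 for the mean of all days and 0.22 for the difference between arms. In data simulated with known changes, limma recovered 83% of 100 genes changed by 1 on the log2 scale at day 7, 86% at day 1, 100% for the mean of all days and 63% for the difference. For changes of 0.5 it recovered 47, 42, 87 and 16%, with 12, 10, 9 and 10 false calls. The changed genes were drawn from those above a minimum mean, so low genes were not covered. Each gene had the same spread in all groups, unlike in the data, where the control replicates of day 1 differed most. The shares for day 1 may therefore be too high.

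The genes named in the text were chosen by a rule set before the data were examined. They are Ddx10, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, replicates that do not overlap and a proper symbol, and the 4 members of each list with the smallest p. Some genes that the rule gives are not reported here, and the genes named in the text for the interaction and the closing part also include those named for another comparison. The gene lists were fixed at the same stage and hold general cell cycle, pluripotency, epithelial, fibroblast, interferon, metabolic, stress and cell type genes. Of these, 22 were tested with camera, with a preset correlation between genes of 0.01 and again with a correlation estimated from the data, and with fry. The reprogramming factors were not tested as a list, and mitochondrial messenger RNAs, absent from the table, were not analysed here. Only 6 of 80 cytosolic ribosomal protein genes were in the table. In simulated data with no effect camera called 0 lists, but there the genes varied independently, unlike in cells. A count adjusted over the list alone uses the Benjamini and Hochberg method on the list's own members.

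For the position on the control course, each library was projected on the line from the mean of control day 0 to the mean of control day 7, and the mean difference at days 1, 3 and 5 was tested by an exact permutation of the arms within days. In simulated data the exact permutation p was 0.593 with no effect, and a move of -0.1 came back as -0.093 (exact permutation p = 0.0093). Overlaps of called genes were set against n1 × n2 / N for independent lists.

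Alternatives tried were quantile scaling, pseudocounts of 0.1 and 5, the replicate number as a block, a fold minimum, fits on the compared libraries alone and fits without each library in turn. Added after the data were seen were a minimum mean of 50, weights per library and the mean of all days without day 1. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.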

Results

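RNA sequencing was performed on embryonic fibroblasts of OG2 mice, which carry a green fluorescent reporter under Oct4 regulatory sequence, during their reprogramming by retroviral Oct4, Sox2, Klf4 and Myc in iCD1 medium. The cells also received an shRNA against luciferase, used as the control, or an shRNA against Ddx10, a DEAD-box RNA helicase known for its part in the assembly of the small ribosomal subunit. The 2 arms were sampled at days 0, 1, 3, 5 and 7 with 2 replicates each, giving 10 groups and 20 libraries. The table held 15757 genes as normalized read counts, which summed to between 15.7 M (control replicate 1 of day 7) and 21.3 M (control replicate 1 of day 0) per library. The step between low values put the depth at about 12.0 M reads in control replicate 2 of day 1 and about 23.7 M in knockdown replicate 2 of day 5, with the other libraries between them. Levels below are mean normalized read counts ± SD of 2 libraries, and fold changes are on the log2(value + 1) scale, which understates changes of low genes.

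Replicates correlated at r = 0.981 to 0.989 across genes. The median absolute log2 difference between replicates was 0.207 in the control group of day 1 and 0.0925 to 0.127 in the other 9 groups. The 4 reprogramming factors were already high at day 0, with Pou5f1 (Oct4) at 14761 ± 1443, Sox2 at 7540 ± 950, Klf4 at 11767 ± 1066 and Myc at 1962 ± 177 in the control. In the knockdown arm Pou5f1 stood at 15086 ± 221, Sox2 at 7273 ± 344, Klf4 at 11363 ± 447 and Myc at 1771 ± 28.9 at that day. These counts cannot separate the viral copies from the cells' own genes.

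Ddx10, the targeted gene (ENSMUSG00000053289, mm10 chromosome 9, 53098635 to 53248053, minus strand), was measured first as a check of the labels. Control levels were 512 ± 16.6, 862 ± 82.9, 822 ± 27.4, 762 ± 47.4 and 815 ± 74.0 at days 0, 1, 3, 5 and 7. Ddx10 stood at 316 ± 4.55, 288 ± 46.8, 331 ± 34.8, 441 ± 20.8 and 529 ± 0.91 in the knockdown libraries of the same days, below both controls on each day. The log2 fold change of Ddx10 was -0.69, -1.58, -1.31, -0.79 and -0.62 (SE 0.12 each), and -0.999 (SE 0.05, limma adjusted p = 5.85e-08) as the mean of all days. The single-day call for Ddx10 was lost at day 0 without knockdown replicate 1 (limma adjusted p = 0.0562) and at day 7 without control replicate 1 (0.0777) or knockdown replicate 2 (0.0502). A limma fit on the compared libraries alone also lost Ddx10 at day 0 (limma adjusted p = 0.186) and day 1 (0.523).

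**Figure D1:**
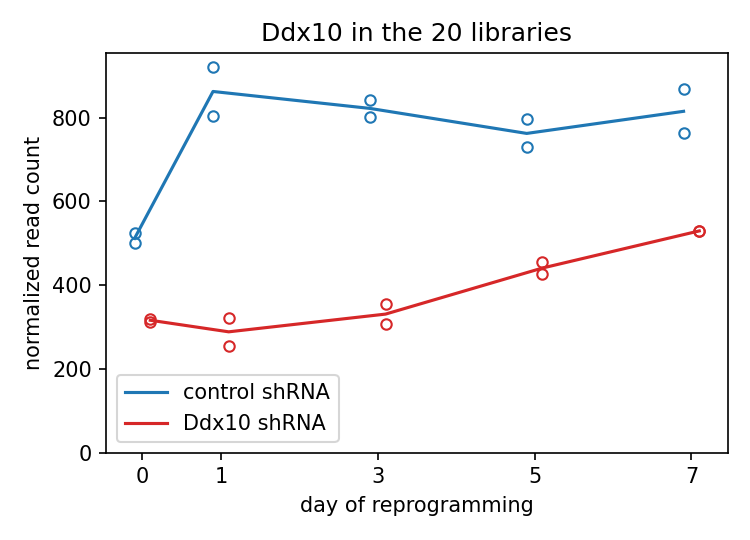
Ddx10 expression (normalized read count, linear axis from 0) against the day of reprogramming, with a circle for each of the 20 libraries and lines through the group means of the control (blue) and knockdown (red) arms. The knockdown libraries lie below the control libraries of the same day, from 316 against 512 at day 0 to 529 against 815 at day 7.

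The control arm was compared across days to describe the course of reprogramming against which the knockdown is read. By day 1, cell cycle genes had risen and genes of resident blood cells had fallen. Of 44 G2 and M phase genes, 42 rose and none fell, among them Hmmr (log2 1.94), a spindle-binding protein, and Kif23 (1.76), a cytokinesis motor (camera adjusted p = 1.45e-16, and 0.0159 with an estimated correlation; 42 rose adjusted over the list alone). Of 44 S phase genes, 41 rose, including Mcm4 (1.12) of the replicative helicase and the polymerase clamp Pcna (0.96), with a camera adjusted p = 6.23e-12 (0.0231 with an estimated correlation; 43 adjusted over the list alone). Among 34 genes of the integrated and unfolded protein stress responses 30 fell and 2 rose, both over all genes and adjusted over the list alone. They included the chaperone gene Calr (-1.55) and the transcription factor gene Xbp1 (-1.71), with a camera adjusted p = 1.21e-11, and 0.000495 with an estimated correlation. Cholesterol biosynthesis genes rose in 22 of 25 (23 adjusted over the list alone) at a camera adjusted p = 1.19e-10, and 0.00584 with an estimated correlation. Of 18 macrophage and blood markers 13 fell and 1 rose, as also adjusted over the list alone, with the lysozyme gene Lyz2 at -5.81 and the growth factor receptor gene Csf1r at -4.85. Their camera adjusted p was 3.21e-05, but adjusted p = 0.0847 with an estimated correlation. Nefl, a neurofilament gene, rose by 5.59, and Aldh3a1, an aldehyde dehydrogenase gene, by 5.55.

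By day 7 the control cells had lost most fibroblast transcripts and gained epithelial, pluripotency and interferon-stimulated ones. Of 44 fibroblast and mesenchymal genes, 34 fell and 6 rose, over all genes and adjusted over the list alone. The falls included those of the actin-binding gene Tagln from 55375 ± 2554 to 88.9 ± 9.92, the smooth muscle actin gene Acta2 (log2 -8.09), the matrix gene Thbs1 (-5.33) and the collagen cross-linking enzyme gene Lox (-5.15). That list passed at a camera adjusted p = 8.13e-09, but not with an estimated correlation (adjusted p = 0.162 with an estimated correlation). Epithelial genes rose in 30 of 33 and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 8.81e-11, and 0.0188 with an estimated correlation). Among the rises were those of the keratin gene Krt8 (6.92), the tight junction gene Cldn3 (6.25), the adhesion gene Epcam (10.11) and the serine protease gene St14 (4.58). The pluripotency list had 33 rises and 1 fall among 38 genes, unchanged when adjusted over the list alone (camera adjusted p = 4.33e-08, and 0.0188 with an estimated correlation). The threonine dehydrogenase gene Tdh, high in mouse embryonic stem cells, rose by 8.78, Sall1 by 4.85 and L1td1 by 4.42. Interferon-stimulated genes rose in 32 of 33 and fell in 1, also when adjusted over the list alone, with Stat2, a signal transducer of interferon receptors, at 3.30. The list passed camera at adjusted p = 2.40e-13 and missed it at adjusted p = 0.162 with an estimated correlation. Immediate early genes fell in 19 of 20, as also adjusted over the list alone, with the phosphatase gene Dusp1 at -3.17 (camera adjusted p = 3.51e-08, but adjusted p = 0.0827 with an estimated correlation). Of 34 stress response genes 31 fell and 2 rose, as also adjusted over the list alone, with Phgdh of serine synthesis at -2.91 (camera adjusted p = 4.65e-09, and 0.00145 with an estimated correlation). The esterase gene Ces1f rose by 10.09.

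In the limma fit, 8664 genes changed in the control between days 0 and 1 (4452 higher, 4212 lower), 10427 by day 3, 11060 by day 5 and 11390 by day 7 (6084 higher, 5306 lower). More genes were higher than lower at day 7, and fewer after quantile scaling (5139 higher, 5913 lower). Intermediate values lay along the same path, with Krt8 at 4.71 and 6.69 and Tagln at -7.79 and -9.23 at days 3 and 5. The retinol receptor gene Stra6 (8.60) and Gad2 (8.39), a GABA-synthesising enzyme gene, were among the rises to day 3, and Tdh rose by 8.25. The median log2 change of all genes to day 7 was 0.09, and -0.08 after quantile scaling, far below the changes named here.

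The knockdown arm made a course of the same kind. From day 0 to day 7, 10576 genes changed (5706 higher, 4870 lower, limma; 4733 higher and 5484 lower after quantile scaling). Epithelial genes rose in 30 of 33 and fell in 1, as also adjusted over the list alone, with Krt8 at 5.95 and the cadherin gene Cdh1 at 7.36 (camera adjusted p = 9.79e-11, and 0.0187 with an estimated correlation). The pluripotency genes rose in 33 of 38 and fell in 1, the same adjusted over the list alone, with Tdh at 10.29 and Sall1 at 4.61 (camera adjusted p = 3.59e-08, and 0.0187 with an estimated correlation). Fibroblast genes fell in 31 of 44 and rose in 10, the same adjusted over the list alone, with Tagln at -7.79 and Lox at -4.40. For this list the camera adjusted p was 6.57e-07, but adjusted p = 0.253 with an estimated correlation.

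The knockdown was then compared with the control at each day, to ask which transcripts differ with the Ddx10 shRNA as reprogramming proceeds. No label names another shRNA against Ddx10 or a rescue. The loss of Ddx10 therefore cannot be told apart from other effects of the shRNA. At day 0, immediate early genes, which answer growth signals and handling within minutes, were lower in the knockdown. Of 20, 8 fell and none rose (12 adjusted over the list alone). They included the transcription factor genes Egr1 (3866 ± 90.8 in the control and 1330 ± 15.7 in the knockdown; log2 -1.54, SE 0.15, limma adjusted p = 0.000149), Nr4a1 (-0.91), Jun (-0.59) and Junb (-0.67). The list passed at a camera adjusted p = 7.18e-11 and missed the threshold at an adjusted p = 0.0608 with an estimated correlation. The heme oxygenase gene Hmox1 rose from 3297 ± 74.3 to 8254 ± 236 (log2 1.32, SE 0.13, limma adjusted p = 0.000131) and the iron exporter gene Slc40a1 from 113 ± 8.14 to 320 ± 79.7 (1.48). The antiproliferative gene Btg2 (-0.64), Tdh (-0.80) and the enolase gene Eno2 (-1.18) fell. In all, 393 genes were higher and 128 lower by limma. That count of 521 fell to 277 without control replicate 2 of day 0 and to 100 without knockdown replicate 1. Named members of other lists were lost in such fits, namely the replication gene Mcm3 (-0.40) without any 1 of the 4 libraries (limma adjusted p = 0.0754 to 0.212) and the growth factor gene Tgfb3 (-0.41) without control replicate 2 (0.0648), knockdown replicate 1 (0.0942) or knockdown replicate 2 (0.0508). The matrix gene Dcn (0.53) lost its call without control replicate 2 (limma adjusted p = 0.128) or knockdown replicate 1 (0.223). After quantile scaling the limma adjusted p was 0.06 for Mcm3 and 0.0549 for Tgfb3, and for Mcm3 it was 0.0862 with a block nested in day and 0.0742 with library weights. A limma fit on the 4 libraries of day 0 alone called 2 genes (2908 at an unadjusted p under 0.05), Egr1 and Hmox1, and none of the others named here.

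At day 1, few genes differed by limma with all 20 libraries, and those that fell included targets of interferon. Besides Ddx10, the falls included the interferon-stimulated genes Xaf1 (803 ± 82.3 in the control and 456 ± 138 in the knockdown; log2 -0.84) and Lgals3bp (-0.79). Outside the lists, the apolipoprotein L gene Apol9b (-1.11) and the ubiquitin-conjugating enzyme gene Ube2l6 (-0.76), both known to answer interferon, fell too. The mitotic entry gene Cdca3 (1802 ± 253 and 1046 ± 63.4; -0.78, SE 0.11, limma adjusted p = 0.00921) was the 1 fall among 44 G2 and M phase genes, of which 10 fell adjusted over the list alone (camera adjusted p = 5.89e-11, but adjusted p = 0.0966 with an estimated correlation). Of 33 interferon-stimulated genes 2 fell and none rose, 18 fell adjusted over the list alone, and the list median was -0.65, but -0.25 and -1.06 without knockdown replicates 1 and 2 (camera adjusted p = 1.90e-19, but adjusted p = 0.146 with an estimated correlation). None of 44 S phase genes passed over all genes and 18 fell adjusted over the list alone (camera adjusted p = 2.57e-13, but adjusted p = 0.0618 with an estimated correlation), with Mcm7 at -0.38. Macrophage markers, none of which passed alone, had a median of 0.51. The 4 higher genes were Slc5a3 (0.63), an inositol transporter gene, Plec (0.58) and Ahnak (0.55), large structural protein genes, and Fam25c, listed at 0 in the control and at 2.11 ± 0.02 in the knockdown, which was named after its values were seen.

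The limma count at day 1 was 23 genes (4 higher, 19 lower), with 2066 at an unadjusted p under 0.05. It rose to 339 without control replicate 1 of day 1 (183 higher, 156 lower), to 743 without control replicate 2 (221 and 522) and to 42 without knockdown replicate 2 (9 and 33), so the balance of directions rests on single libraries. Without knockdown replicate 1 it was 18 (9 and 9), and it was 0 in a limma fit on the 4 libraries of day 1 alone (748 at an unadjusted p under 0.05). Without knockdown replicate 1 the limma adjusted p became 0.115 for Xaf1 (log2 -0.53), 0.18 for Lgals3bp (-0.52), 0.0702 for Ube2l6 (-0.67) and 0.18 for Apol9b (-0.70). Plec and Ahnak lost their calls without either knockdown library (Plec 0.18 and 0.0655, Ahnak 0.059 and 0.133, for replicates 1 and 2), and Slc5a3 without either of them (0.179 and 0.133) or control replicate 1 (0.0626). After quantile scaling the limma adjusted p was 0.0653 for Lgals3bp, 0.0544 for Ahnak and 0.0545 for Slc5a3, and with a pseudocount of 5 it was 0.0551 for Slc5a3. With the replicate block the limma adjusted p was 0.0665 for Apol9b, 0.0586 for Plec, 0.0541 for Ahnak and 0.0665 for Slc5a3, and with a block nested in day 0.0655 for Plec and 0.0619 for Slc5a3. With library weights, chosen after the result was seen, the limma adjusted p was 0.486 for Xaf1, 0.613 for Lgals3bp, 0.239 for Ube2l6, 0.525 for Apol9b, 0.179 for Cdca3, 0.486 for Plec and Ahnak and 0.628 for Slc5a3, and Ddx10 alone was called.

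At day 3 the cell division genes stood lower in the knockdown. Of 44 G2 and M phase genes 24 fell and none rose (37 adjusted over the list alone; camera adjusted p = 3.01e-30, and 0.0053 with an estimated correlation). The mitotic kinase gene Plk1 stood at 1869 ± 101 in the control and 1213 ± 41.1 in the knockdown (log2 -0.62, SE 0.08, limma adjusted p = 0.00142), with Cdca3 at -0.75 and the kinase gene Aurka at -0.60. Of 44 S phase genes 15 fell and none rose (28 adjusted over the list alone; camera adjusted p = 5.76e-20, and 0.0074 with an estimated correlation), among them the DNA ligase gene Lig1 (2056 ± 242 and 1254 ± 106; -0.71) and Mcm5 (-0.60) of the replicative helicase. Ribosome biogenesis factors, the group to which Ddx10 belongs, fell in 8 of 82 with no rise (10 adjusted over the list alone), with Nolc1 at -0.37 and Lyar at -0.60, nucleolar proteins. Camera called the list at adjusted p = 8.41e-10, and did not at adjusted p = 0.0684 with an estimated correlation. Fibroblast genes rose in 11 of 44 and fell in 1 (19 and 1 adjusted over the list alone), with Lox at 0.71 and Thbs1 at 0.49 (camera adjusted p = 2.75e-09, but adjusted p = 0.155 with an estimated correlation). Adipocyte markers rose in 1 of 5 (1 adjusted over the list alone; camera adjusted p = 0.0302, but adjusted p = 0.155 with an estimated correlation), a call lost without control replicate 2 (camera adjusted p = 0.0525). Of 33 epithelial genes 3 fell (3 adjusted over the list alone), with Krt8 at -1.05 and Cdh1 at -1.11. This call had a camera adjusted p = 0.00132, but adjusted p = 0.155 with an estimated correlation. Senescence and secretory genes rose in 3 of 25, with Igfbp3 at 0.49 among them, and 6 adjusted over the list alone. That gave a camera adjusted p = 0.000127, but adjusted p = 0.117 with an estimated correlation.

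Other day 3 changes were falls of the nucleotide hydrolase gene Samhd1 (2744 ± 50.1 and 1546 ± 137; log2 -0.83), the transcription factor genes Klf2 (-0.91) and Fosb (-1.63) and the DNA methyltransferase gene Dnmt3b (-0.97). Rises included those of the matrix-associated gene Srpx (1.01) and the protease gene Corin (0.96). The limma fit called 751 genes (396 higher, 355 lower), and 296, 137, 74 and 160 without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2 of day 3. Cdh1 lost its call without any 1 of those 4 libraries (limma adjusted p = 0.0765 to 0.171). Without knockdown replicate 1 the limma adjusted p was 0.0514 for Aurka, 0.0548 for Samhd1, 0.0925 for Nolc1, 0.0733 for Lyar, 0.0501 for Corin, 0.178 for Dnmt3b and 0.0828 for Igfbp3. Without control replicate 2 it was 0.0782 for Nolc1, 0.0629 for Fosb, 0.0782 for Thbs1, 0.0894 for Lyar, 0.0658 for Corin, 0.128 for Dnmt3b and 0.081 for Igfbp3. Nolc1 (0.0505), Thbs1 (0.0638), Lyar (0.0689) and Corin (0.061) were also lost without knockdown replicate 2, and Dnmt3b (0.0681) without control replicate 1. After quantile scaling Thbs1 stood at 0.45 with a limma adjusted p = 0.362.

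**Figure D2:**
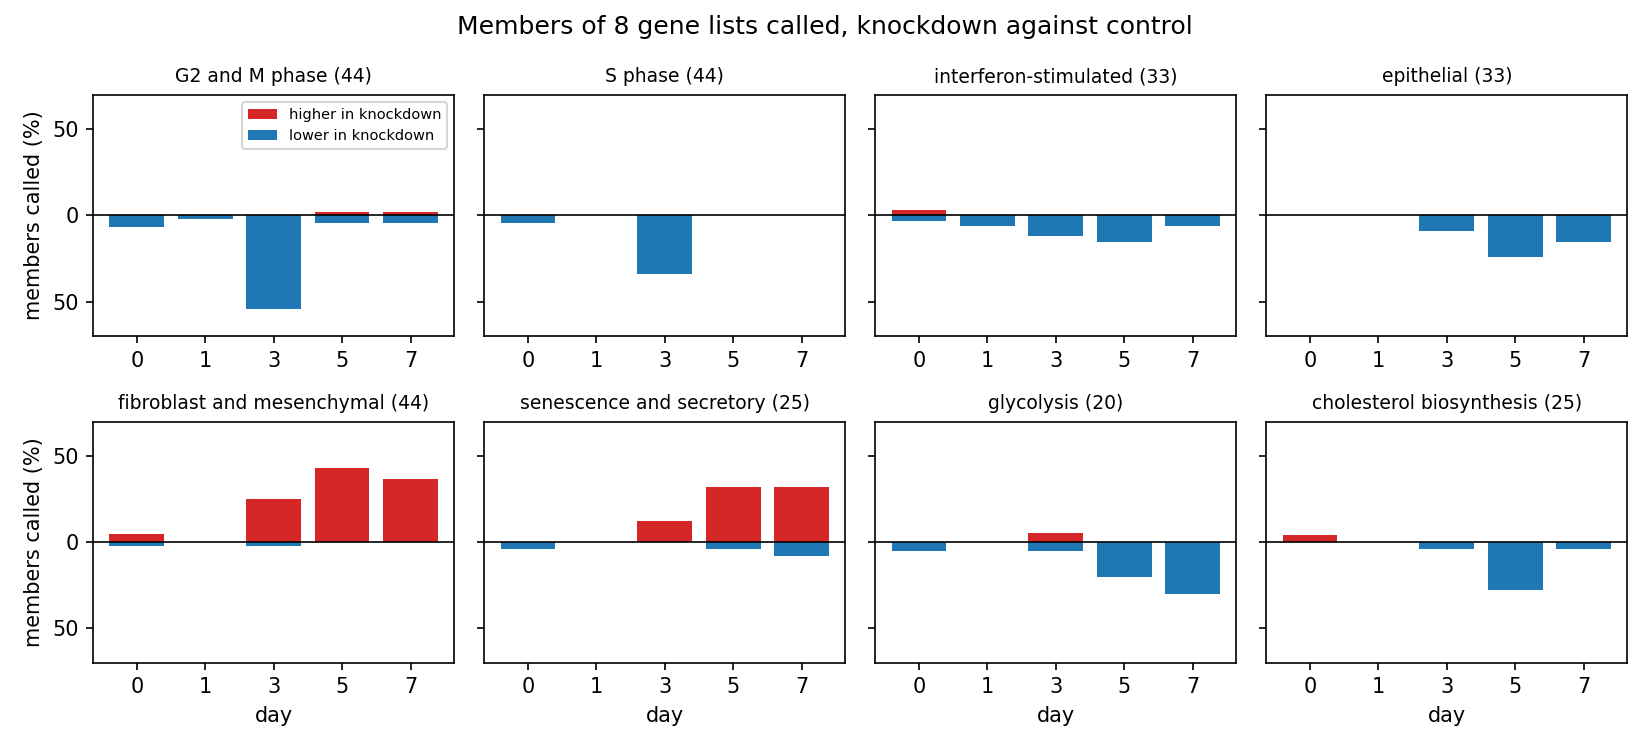
Share of measured members (percent, number measured in brackets) of 8 gene lists called by limma in the knockdown against the control at days 0, 1, 3, 5 and 7, higher in red above the line and lower in blue below it. The cell cycle bars reach furthest at day 3, with 24 of 44 G2 and M phase genes lower, and the fibroblast bars at day 5, with 19 of 44 genes higher.

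At day 5, epithelial genes stood lower and fibroblast genes higher in the knockdown than in the control. Of 33 epithelial genes 8 fell and none rose (13 adjusted over the list alone; camera adjusted p = 1.81e-10, and 0.0305 with an estimated correlation). They included the keratin genes Krt8 (4032 ± 244 in the control and 1304 ± 52.9 in the knockdown; log2 -1.63, SE 0.13, limma adjusted p = 1.14e-05), Krt19 (-1.12) and Krt18 (-1.04) and the tight junction gene Cldn4 (1027 ± 12.0 and 279 ± 8.85; -1.88). Of 44 fibroblast genes 19 rose and none fell (33 adjusted over the list alone; camera adjusted p = 4.72e-15, but adjusted p = 0.0875 with an estimated correlation), with Lox at 0.69, Tagln at 1.14 and the collagen gene Col6a3 at 0.73. Adipocyte markers rose in 2 of 5 (4 adjusted over the list alone; camera adjusted p = 0.000267, but adjusted p = 0.0544 with an estimated correlation). Senescence and secretory genes rose in 8 of 25 and fell in 1 (10 and 1 adjusted over the list alone), among them the urokinase gene Plau (149 ± 18.6 and 513 ± 65.0; 1.78), the matrix metalloproteinase genes Mmp10 (1.69) and Mmp13 (1.66), and Igfbp3 (0.78). Their camera adjusted p was 0.00154, but adjusted p = 0.243 with an estimated correlation. Cholesterol biosynthesis genes fell in 7 of 25 with no rise (13 adjusted over the list alone; camera adjusted p = 5.18e-09, and 0.0205 with an estimated correlation), with Fdps and Fdft1 both at -0.34. The lactate exporter gene Slc16a3 fell from 299 ± 158 to 23.2 ± 2.54 (-3.53, SE 0.36) and the aldolase gene Aldoc by 1.36. They were among 4 falls of 20 glycolysis genes (5 adjusted over the list alone; camera adjusted p = 0.000768, but adjusted p = 0.292 with an estimated correlation).

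Also at day 5, interferon-stimulated genes fell in 5 of 33 with no rise (6 adjusted over the list alone), with Samhd1 at -0.86 and Ifit2 at -0.67 (camera adjusted p = 0.000228, but adjusted p = 0.414 with an estimated correlation). The GTPase gene Tgtp2, which shares sequence with a near copy, fell by 2.65. Pluripotency genes fell in 4 of 38 and rose in 1, as also adjusted over the list alone, with Klf2 at -1.06, the RNA-binding protein gene Lin28a at -1.90 and Tdh at 0.49. The list passed camera at adjusted p = 0.00711 and missed it at adjusted p = 0.243 with an estimated correlation. Of 34 p53 targets 6 rose and 3 fell (13 and 5 adjusted over the list alone), with the p53 ligase gene Mdm2 at 0.62 and Btg2 at -0.59. For this list the camera adjusted p was 0.0392, but adjusted p = 0.292 with an estimated correlation. The semaphorin gene Sema7a rose by 1.53. The limma fit called 1376 genes (919 higher, 457 lower), and 459 without control replicate 1, 477 without knockdown replicate 1 and 835 without knockdown replicate 2 of day 5. The epithelial call with an estimated correlation was lost without control replicate 1 (camera adjusted p = 0.0545) or knockdown replicate 2 (0.0809), and the p53 call with the preset one without control replicate 1 (0.0994) or knockdown replicate 1 (0.215). Without control replicate 1 or knockdown replicate 1 the limma adjusted p was 0.0506 or 0.0586 for Tdh, 0.0636 or 0.0831 for Fdps, 0.0711 or 0.0909 for Fdft1 and 0.0817 or 0.0586 for Mmp13. The fold of Mmp13 was 0.94 without control replicate 1 and 2.38 without control replicate 2, and in a fit on the libraries of day 5 alone its limma adjusted p was 0.0964. Lin28a lost its call without any 1 of the 4 libraries (limma adjusted p = 0.0592 to 0.239), with a pseudocount of 0.1 (0.162), with a block nested in day (0.0695) and on the libraries of day 5 alone (0.073).

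At day 7 some epithelial and glycolysis genes were lower and some fibroblast and secretory genes higher, in lists that passed camera with the preset correlation only. Fibroblast genes rose in 16 of 44 with no fall (29 adjusted over the list alone; camera adjusted p = 4.26e-15, but adjusted p = 0.116 with an estimated correlation). Tagln stood at 88.9 ± 9.92 in the control and 199 ± 17.4 in the knockdown (log2 1.16, SE 0.14), and Lox differed by 0.80. Adipocyte markers rose in 3 of 5 (4 adjusted over the list alone; camera adjusted p = 0.00105, but adjusted p = 0.116 with an estimated correlation). Epithelial genes fell in 5 of 33 with no rise (7 adjusted over the list alone; camera adjusted p = 9.22e-09, but adjusted p = 0.108 with an estimated correlation). Krt8 stood at 4715 ± 335 and 2071 ± 137 (-1.19, SE 0.13, limma adjusted p = 0.000111), with Krt19 at -1.41 and Krt18 at -1.19. Of 25 senescence and secretory genes 8 rose and 2 fell, as also adjusted over the list alone, with Plau at 1.57, Mmp10 at 1.82 and Igfbp3 at 0.76. Camera called the list at adjusted p = 0.00165, and did not at adjusted p = 0.222 with an estimated correlation. Glycolysis genes fell in 6 of 20 with no rise (8 adjusted over the list alone), led by Slc16a3 (718 ± 245 and 69.8 ± 6.69; -3.30), with Aldoc at -1.07, the isomerase gene Tpi1 at -0.48 and the lactate dehydrogenase gene Ldha at -0.44. This call had a camera adjusted p = 1.18e-05, but adjusted p = 0.222 with an estimated correlation. Egln3, an oxygen-sensing hydroxylase gene, fell from 476 ± 164 to 160 ± 19.7 (-1.52).

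The pluripotency list had 1 rise and 1 fall among 38 genes at day 7, as also adjusted over the list alone, with Tdh at 0.70 and Klf2 at -0.70, and its camera adjusted p of 0.0608 missed the threshold. Dppa4 stood at -1.95 with a limma adjusted p = 0.0802, and at -2.77 without knockdown replicate 1 and -1.14 without knockdown replicate 2. Of 44 S phase genes 0 passed by limma there, over all genes or adjusted over the list alone (camera adjusted p = 0.513). Further rises at day 7 were those of the semaphorin gene Sema3e (1.38), the thyrotropin receptor gene Tshr (1.28), the vascular growth factor receptor gene Kdr (1.17) and Mdm2 (0.42). Further falls were those of the reductase gene Cbr2 (-1.76), the immunoproteasome gene Psmb9 (-1.59) and the serine protease gene Tmprss2 (-1.55). The limma fit called 972 genes (733 higher, 239 lower), and 357, 512, 553 and 286 without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2 of day 7. Calls were lost for Psmb9 (0.0555 to 0.116) and Tmprss2 (0.0578 to 0.136) without any 1 of these 4 libraries, for Cbr2 without knockdown replicate 2 (0.0529) and for Ldha without control replicate 1 (0.0743), as limma adjusted p. Tmprss2 also lost its call with a pseudocount of 0.1 (limma adjusted p = 0.09) and with a block nested in day (0.0507).

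**Figure D3:**
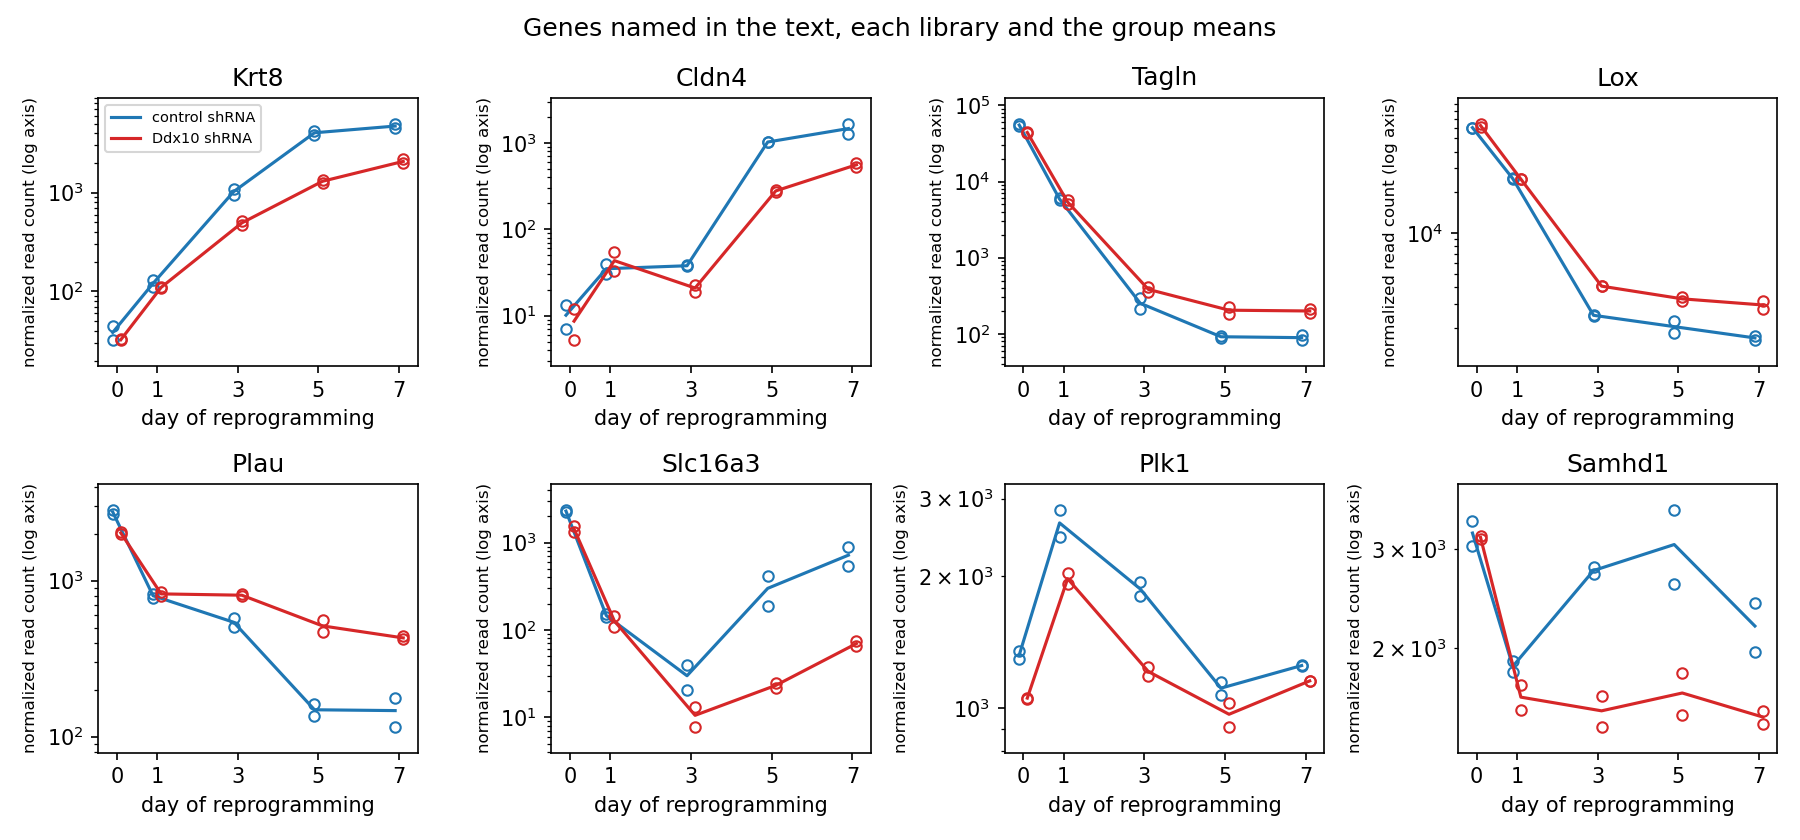
Normalized read counts (log axis) of 8 genes against the day of reprogramming, with a circle for each library and lines through the group means of the control (blue) and knockdown (red) arms. Krt8 and Cldn4 climb less in the knockdown, Tagln, Lox and Plau stay higher from day 3 on, Slc16a3 recovers less, and Plk1 and Samhd1 lie lower at day 3.

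Days 5 and 7 share no library. Their calls of the knockdown effect overlapped in 522 higher genes (42.8 for independent lists) and 158 lower genes (6.9). Across genes with a mean above 50, used for each r here, their fold changes correlated at r = 0.717. For days 3 and 5 r was 0.497, for days 3 and 7 it was 0.411, and for day 0 against days 5 and 7 it was -0.019 and -0.036.

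As the mean of all days, cell cycle and cholesterol biosynthesis genes were lower and adipocyte markers higher in the knockdown with either correlation, though not in every fit without 1 library. Genes that changed included rises of the neurofilament gene Nefm (log2 0.77, SE 0.05, limma adjusted p = 2.59e-07), Corin (0.81), the signalling gene Rasgrp3 (0.87) and the peroxisomal transporter gene Abcd2 (0.88). They also included falls of Nlrc5 (-0.99), a transactivator of major histocompatibility class I genes, the class I gene H2-K1 (-0.66), whose reads overlap with those of related genes, and the planar polarity cadherin gene Celsr1 (-0.84). G2 and M phase genes fell in 23 of 44 (31 adjusted over the list alone), with Cdca3 at -0.49 and Plk1 at -0.34. S phase genes fell in 19 of 44 (22 adjusted over the list alone), with Mcm7 at -0.29 and Lig1 at -0.33. Their camera adjusted p was 2.44e-14 and 2.98e-11, and 0.0354 for both with an estimated correlation. These falls were uneven over the days. At days 1 and 3 the medians of both lists were lower in both knockdown libraries than in both controls. Relative to each gene's mean over all libraries, the G2 and M phase medians at day 0 were -0.44 and -0.43 in the control. They were -0.39 and -0.4 in the knockdown. The S phase medians at day 7 were 0.01 and 0.02 in the control and 0.01 in both knockdown libraries. Cholesterol biosynthesis genes fell in 9 of 25 (10 adjusted over the list alone), with the squalene synthase gene Fdft1 at -0.24 and Nsdhl at -0.20 (camera adjusted p = 1.88e-06, and 0.0354 with an estimated correlation). Adipocyte markers rose in 3 of 5, as also adjusted over the list alone, with the lipoprotein lipase gene Lpl at 0.47 and the fatty acid transporter gene Cd36 at 1.42 (camera adjusted p = 0.000194, and 0.0429 with an estimated correlation). With an estimated correlation these calls were not robust: of 20 fits without 1 library, 8 ended the call of the cholesterol list, 9 that of G2 and M phase genes, 9 that of S phase genes and 15 that of adipocyte markers (camera adjusted p = 0.0504 to 0.0739).

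Other lists passed for the mean of all days with the preset correlation and missed the threshold with an estimated one. Fibroblast genes rose in 23 of 44 and fell in 1 (28 and 1 adjusted over the list alone), with Lox at 0.45 and Tagln at 0.49. That gave a camera adjusted p = 5.12e-10, but adjusted p = 0.122 with an estimated correlation. At day 0 this list had pointed down, with a median of -0.18 but 1 fall and 2 rises by limma (1 and 2 adjusted over the list alone; camera adjusted p = 0.00175, but adjusted p = 0.513 with an estimated correlation). Interferon-stimulated genes fell in 12 of 33 (15 adjusted over the list alone), with Samhd1 at -0.49. Their camera adjusted p was 1.24e-07, but adjusted p = 0.239 with an estimated correlation. Epithelial genes fell in 12 of 33 (15 adjusted over the list alone), with Krt8 at -0.84 and Krt19 at -0.55 (camera adjusted p = 7.57e-07; adjusted p = 0.0533 with an estimated correlation). Glycolysis genes fell in 12 of 20 with 1 rise, as also adjusted over the list alone, with Slc16a3 at -1.82 and Tpi1 at -0.28. The list passed camera at adjusted p = 1.38e-06 and missed it at adjusted p = 0.137 with an estimated correlation. Of 6 measured cytosolic ribosomal protein genes 4 fell, as also adjusted over the list alone, with Rpsa at -0.28 and Rplp0 at -0.21. For this list the camera adjusted p was 0.000521, but adjusted p = 0.14 with an estimated correlation. Ribosome biogenesis factors fell in 13 of 82 (3 adjusted over the list alone), with the RNA polymerase subunit gene Polr1c at -0.23 and the rRNA gene activator Ubtf at -0.11. Camera called the list at adjusted p = 0.00249, and did not at adjusted p = 0.235 with an estimated correlation.

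Senescence and secretory genes rose in 9 of 25 and fell in 1 (10 and 3 adjusted over the list alone), with Igfbp3 at 0.45 and Plau at 0.71. This call had a camera adjusted p = 0.00239, but adjusted p = 0.14 with an estimated correlation. Of 34 p53 targets 15 rose and 4 fell (17 and 6 adjusted over the list alone), with Mdm2 at 0.31 and Btg2 at -0.33. That gave a camera adjusted p = 0.00617, but adjusted p = 0.122 with an estimated correlation. Stress response genes fell in 10 of 34 and rose in 3, as also adjusted over the list alone, with the serine synthesis gene Psat1 at -0.31. Their camera adjusted p was 0.0261, but adjusted p = 0.109 with an estimated correlation. Immediate early genes fell in 4 of 20 and rose in 1 (6 and 2 adjusted over the list alone), with Fosl1 at 0.37 as the rise (camera adjusted p = 0.0259; adjusted p = 0.322 with an estimated correlation). This mean joins opposite directions, since 4 of 20 fell at day 3 (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0139, but adjusted p = 0.343 with an estimated correlation) and 4 rose at day 5. At day 5, 6 rose adjusted over the list alone, with a camera adjusted p = 0.00687, but adjusted p = 0.297 with an estimated correlation. Pluripotency genes fell in 3 of 38, as also adjusted over the list alone, namely Klf2 (-0.58), Mybl2 (-0.28) and Lin28a (-0.97). That share is near the share of all genes that fell (1175 of 15757). The list passed camera at adjusted p = 0.0295 and missed it at adjusted p = 0.235 with an estimated correlation.

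The remaining lists missed the threshold for the mean of all days. By limma, macrophage and blood markers had 3 rises and 1 fall of 18 (camera adjusted p = 0.0691), endothelial markers 2 rises of 12 (camera adjusted p = 0.223) and 2-cell-like genes none of 9 (camera adjusted p = 0.374). By limma, Polycomb genes had 1 fall of 33 (camera adjusted p = 0.438) and muscle markers 2 rises of 10 (camera adjusted p = 0.764). By limma, neural markers had 3 rises and 1 fall of 15, and markers of trophoblast, primitive endoderm and epidermis 3 rises and 3 falls of 19 (camera adjusted p = 0.913 for both). Adjusted over the list alone, neural markers had 4 rises and 5 falls, the trophoblast list 3 and 4, and Polycomb genes none, and the other 4 lists kept those counts. For neural markers the median (-0.18) and mean (-0.13) lay below 0 while the test pointed up. For muscle markers the mean was -0.01 with a median of 0.03 and an upward test, and for the trophoblast list the median was 0.07 with a mean of -0.01 and a downward test.

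The immediate early call was lost without control replicate 1 of day 1 (camera adjusted p = 0.118) and after quantile scaling (0.0873). The stress response call was lost after quantile scaling (camera adjusted p = 0.0825) and without day 1 (0.0717), a fit chosen after the result was seen. The pluripotency call was lost without control replicate 2 of day 0 (0.0623), control replicate 1 of day 1 (0.0664), knockdown replicate 2 of day 3 (0.0556) or knockdown replicate 2 of day 7 (0.0806), each a camera adjusted p. By limma 2799 genes differed as the mean of all days (1624 higher, 1175 lower), and 15 of 22 lists passed camera with the preset correlation, 4 with an estimated one. Other divisions of the same libraries within each day called a median of 0 genes and 6 lists, so a list call with the preset correlation alone is weak evidence.

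The change from day 0 to day 7 was compared between the arms as an interaction. Fibroblast genes fell less in the knockdown, with 18 of 44 members higher and none lower in the difference (23 and 1 adjusted over the list alone), such as Tagln (log2 difference 1.48) and Lox (0.75). Epithelial genes rose less, with 5 of 33 lower, as also adjusted over the list alone, such as Krt19 (-1.14), Krt18 (-1.23) and Krt8 (-0.97). Their camera adjusted p was 2.36e-13 and 0.0001, and each had an adjusted p = 0.149 with an estimated correlation. Plau, which fell by 4.25 in the control, had a difference of 2.02 (SE 0.21, limma adjusted p = 0.00028), Slc40a1 of -2.67, Slc16a3 of -2.62, the guanylate-binding protein gene Gbp4 of -1.88 and the cytokine gene Lif of 1.88. Immediate early genes, lower in the knockdown at day 0, were higher in the difference in 8 of 20, as also adjusted over the list alone, with Egr1 at 1.66, Nr4a1 at 1.16 and Jun at 0.74 (camera adjusted p = 1.15e-06, but adjusted p = 0.149 with an estimated correlation). Tdh (1.5) and Igfbp4 (1.24) were higher too, and Tdh had been lower in the knockdown at day 0 (-0.799). Foxs1 was listed at 0 in the control at day 7 and at 10.1 ± 2.08 in the knockdown. Ddx10 itself differed by 0.07 (limma adjusted p = 0.847), with a sign that flipped after quantile scaling.

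The limma fit called 1005 genes for this difference (617 higher, 388 lower). Leaving out 1 library gave 601 without control replicate 1 and 371 without knockdown replicate 1 of day 0, and 343, 563, 581 and 283 without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2 of day 7. The call of Krt8 was lost without knockdown replicate 2 of day 7 (limma adjusted p = 0.0521).

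To place each library on the control course, its log2 values were projected on the axis from control day 0 (set to 0) to control day 7 (set to 1). Control libraries lay at 0.367 ± 0.013, 0.717 ± 0.011 and 0.933 ± 0.0157 at days 1, 3 and 5, and knockdown libraries at 0.380 ± 0.0107, 0.673 ± 0.0008 and 0.848 ± 0.0073 (SD, 2 libraries each). The differences were 0.013, -0.045 and -0.085, and their mean was -0.039 (exact two-sided permutation p = 0.0463 over 216 assignments, the smallest possible being 0.0093). The p rose above 0.05 without any 1 of 9 of the 12 libraries, being 0.0833 without control replicate 2 or knockdown replicate 1 of day 1, and 0.0648 and 0.0833 without control replicates 1 and 2 of day 3, by the exact permutation test. It was 0.0741 and 0.0833 without knockdown replicates 1 and 2 of day 3, 0.0556 without control replicate 1 or knockdown replicate 1 of day 5, and 0.0648 without knockdown replicate 2 of day 5, each an exact permutation p. By the same test it was 0.0556 along the first principal component of the control libraries and 0.125 with the replicate block. At day 0 the knockdown stood at 0.047 ± 0.0066 and at day 7 at 0.911 ± 0.0192, against 0 and 1 for the control by construction.

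**Figure D4:**
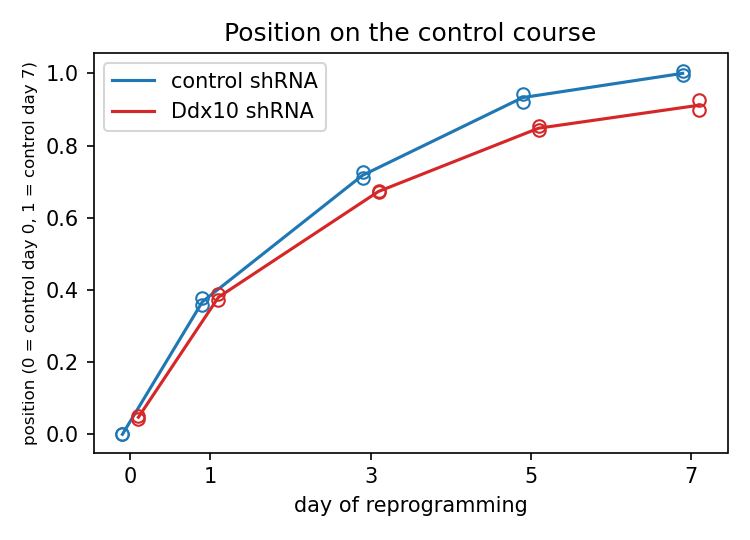
Position of each library on the control course (no unit; 0 is the mean of control day 0 and 1 that of control day 7) against the day of reprogramming, with circles for libraries and lines through group means. Knockdown libraries (red) lie below control libraries (blue) at days 3, 5 and 7, with group means lower by 0.045, 0.085 and 0.089, above them at day 0 (by 0.047), and among them at day 1.

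The knockdown effect at day 7 was set against the control course from day 0 to day 5, which shares no library with it. Of the 239 genes lower in the knockdown at day 7, 166 (69.5%) had risen in the control course, against 90 for independent lists, and 37 had fallen (77.7 for independent lists). Of the 733 higher genes 520 (70.9%) had fallen in the control course, against 238.4, and 123 had risen (276.1). Krt8 (6.69 in the course and -1.19 in the knockdown effect) and Tagln (-9.23 and 1.16) were among the 686 genes that moved against it, while 160 moved with it. Set against the control course to day 3 instead, 537 genes moved against it and 287 with it.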

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

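The tests of the day 5 effect against the control course, of an earlier point on that course, of day 0 cells, of single libraries of day 1 and of blood cells were chosen only after the result was seen, while the splits of the samples were set beforehand.

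The change from day 0 to day 7 differed between the arms, by limma's test of that difference, in 1005 genes. Among the genes named in the text it differed in 42. The difference, which is the change in the knockdown less that in the control, was higher in 27 and lower in 15. It is not a level at day 7. Some genes had differed at day 0 already, which makes up a large part of their differences. Lower in the knockdown at day 0 were Egr1, Nr4a1, Jun, Junb, Eno2 (log2 -1.181), Tdh (-0.799) and Tgfb3 (-0.411). Hmox1 and Slc40a1 (1.477) were higher at that day. Fibroblast and secretory genes were higher, with Tagln at 1.48, Acta2 at 1.06, Lox at 0.75, Col6a3 at 0.83, Thbs1 at 0.52, Igfbp3 at 0.53, Igfbp4 at 1.24, Plau at 2.02, Mmp10 at 1.90 and Tgfb3 at 0.75. So were the immediate early genes Egr1 (1.66), Nr4a1 (1.16), Jun (0.74), Junb (0.73) and Fosl1 (1.2), and Eno2 (1.23), Kdr (1.39), Lif (1.88), Nefm (0.86), Oas2 (1.66), Rasgrp3 (1.13), Sema3e (1.24), Sema7a (0.85), Srpx (0.88), Tdh (1.5) and Tshr (0.93). Foxs1, listed at 0 in the control at day 7, had 3.98 on the log2(value + 1) scale, which is no fold. Lower were Krt8 (-0.97), Krt18 (-1.23), Krt19 (-1.14), Cldn3 (-1.2), Slc16a3 (-2.62), Slc40a1 (-2.67), Hmox1 (-1.24), Aldoc (-0.97), Aldh3a1 (-1.13), Ces1f (-1.27), Egln3 (-1.43), Gbp4 (-1.88), H2-K1 (-0.92), Psmb9 (-1.83) and Xaf1 (-0.72).

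In 27 of these 42 genes the call held in each of 8 fits without 1 library. Cldn3, Rasgrp3 and Xaf1 lost it in 8 such fits, Aldoc, Oas2, Psmb9 and Sema7a in 7, Srpx in 6, Igfbp3 and Thbs1 in 5, Tshr in 4 and Eno2 in 3. Without knockdown replicate 2 of day 7 the limma adjusted p was 0.052 for Ces1f, 0.0558 for Egln3 and 0.0521 for Krt8, and these 3 kept their calls in the other 7 fits. For Tshr it was 0.0716 and 0.078 without control replicate 1 and knockdown replicate 1 of day 0, and 0.0749 and 0.0889 without control replicate 1 and knockdown replicate 2 of day 7. For Eno2 it was 0.0597 without control replicate 1 of day 0, 0.0724 without control replicate 1 of day 7 and 0.0754 without knockdown replicate 2 of day 7.

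By the same test 7 lists differed between the arms with the preset correlation of camera. The camera adjusted p was 2.36e-13 for fibroblast genes, 1.15e-06 for immediate early genes, 0.0001 for epithelial genes and 0.00224 for senescence and secretory genes. It was 0.00844 for p53 targets, 0.0132 for stress response genes and 0.0151 for interferon-stimulated genes. With an estimated correlation 0 of the 7 passed, with a camera adjusted p of 0.193 for senescence genes, 0.711 for interferon-stimulated genes and 0.149 for the other 5. With the preset correlation the call of interferon-stimulated genes was lost without control replicate 1 of day 0 (0.132), knockdown replicate 1 of day 0 (0.173) or control replicate 1 of day 7 (0.0607), and that of stress response genes without control replicate 2 of day 0 (0.0711), each a camera adjusted p.

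The mean difference between the arms over all days was set against other splits of the 20 libraries, made within days only, with 100 splits in all. Only 1 of the 100, the real one, called as many genes (2799, highest other 2210), so a count that large was rare among these splits. The same held for the lists with the preset correlation, where 1 of 100 splits, the real one, reached 15 and the highest other 12. It also held for the size of the Ddx10 change, where 1 of 100 reached 1.0 and the highest other was 0.74. The splits were a sample of those possible, and the one with 2210 genes divided 18 of the 20 libraries as the real one does. They cannot tell the shRNA from any other difference between the arms. The other splits called a median of 0 genes but 6 lists, so the preset correlation may understate how far members of a list vary together, and single list calls deserve less weight than their number.

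Of the genes called in the knockdown at day 5, 343 of 457 lower ones rose and 667 of 919 higher ones fell in the control course to day 7 (176.5 and 309.5 for independent lists), and the effect at day 7 opposes the control course to day 5 likewise, as a slower course or cells left behind would give. At day 5, where the knockdown matched control day 4.17 best, 26.7% of the 1376 called genes were still called against that earlier point (2.5 to 32.4% in fits without 1 library), 527 genes in all were called against it, and the median change of the 1376 went from 0.57 to 0.29, so a slower course may account for part of the effect. At day 7, with control day 6.09 as the best match, 83.2% of 972 were still called, 1211 genes in all were called against it and the median change went from 0.57 to 0.5, but the share ran from 14.8 to 92.4% without 1 library, so a slower course cannot be told apart from a different state there. The best match for day 7 itself ran from control day 4.42 to 6.18 without 1 library. Both matches were sought only up to the same control day, so a later one could not be found. They were fitted to the same knockdown libraries, and the genes had been chosen with control libraries that the match partly replaced. Part of a drop in calls or in median change can therefore come from the method itself. On the axis of the control course, knockdown day 7 (0.911) lay below control day 5 (0.933). Cells still in their day 0 state could account for only 6% of the 733 higher genes. That holds at the share of 1.45% that the strongest falling genes would need. A gene counted where such cells gave at least as much of its rise as they left unexplained. The interval of 4.4 to 8% treats genes as independent and does not measure the spread between libraries. A share at the upper quartile of 2.56% would dilute a gene by -0.037 (log2). By contrast, the 457 genes lower at day 5 had a median of -0.35 in the libraries of day 7 (-0.37 to -0.33 without 1 library). Non-reprogramming cells that have left the day 0 state stay open, and with them an effect of Ddx10 on reprogramming itself as a hypothesis.

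Interferon-stimulated genes were lower in the knockdown at day 1, where the control libraries differ most from each other, though 2 of 33 passed alone and the list had an adjusted p = 0.146 with an estimated correlation of camera. Without control replicate 2 of that day the list median was still -0.51 (-0.69 to -0.32, 2 standard errors over the genes of the list), and -0.83 without control replicate 1. The lower median thus did not rest on control replicate 2 alone. Without knockdown replicate 1 the list median was -0.25 (-0.36 to -0.13), too near the bound of -0.2, and -1.06 without knockdown replicate 2. A knockdown library that stands apart therefore cannot be told apart from an effect of the arm. These intervals treat genes as independent and do not measure the spread between libraries. Fewer blood cells in the knockdown cultures would lower macrophage markers, but their median was 0.51 (0.37 to 0.53 without 1 library). Its bootstrap interval, also over genes, was 0.02 to 0.82. Lyz2 stood at 35.2 ± 5.26 in the control and 66.4 ± 20.9 in the knockdown, Cd68 at 150 ± 24.5 and 151 ± 3.6 and Csf1r at 7.14 ± 0.17 and 13.3 ± 2.96. Relative to each gene's mean over all libraries, the medians of the interferon-stimulated list were -1.05 and -0.82 in the control and -2.04 and -1.41 in the knockdown, and those of the macrophage and blood markers -0.64 and -0.95 against -0.59 and -0.7, closer together than the 0.51 of the fold changes. A difference in the response to the virus or to its dose stays open and was not tested, and so does an effect of Ddx10 on interferon signalling.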

How the results depend on the processing

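Fits without each library, quantile scaling, the pseudocounts, the replicate block, the fold minimum and the fits on compared libraries alone were planned, while the minimum mean of 50, the weights per library and the fits without day 1 were chosen only after the result was seen. A filter on low values against none could not be compared, because the planned filter removed 0 genes. The planned DESeq2 test needs read counts and was not run, and for the mean of all days a fit on the compared libraries alone is the fit of all libraries.

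Of 186 values of named genes 183 were past the threshold, and 142 of them stayed past it in every setting, 32 were lost in a fit without 1 library, 24 in another setting, and 0 changed sign. The fold minimum was not applied to these single values and is not among the settings counted. These 186 values leave out many of the genes listed above for the difference between the arms, such as Cldn3, Rasgrp3 and Xaf1. The losses of those calls are given there and are not in this tally. The Ddx10 difference between the arms in the change from day 0 to day 7 (0.07, not called) changed sign with quantile scaling (-0.006). It also did so without control replicate 2 of day 7 (-0.018, and up to 0.167 without control replicate 1). For the mean of all days, Ddx10 ran from -1.033 to -0.966 without 1 library.

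Quantile scaling gave 304 genes at day 0 (521 before) and 13 at day 1 (23). Pseudocounts of 0.1 and 5 gave 40 and 14 at day 1. Where a count moved in these settings the cause was not tested. A fold minimum of 2 left, by construction, 87, 4, 70, 251 and 193 genes at days 0, 1, 3, 5 and 7 and 59 for the mean of all days. It left 3228, 5031, 5876 and 6335 in the control course to days 1, 3, 5 and 7, 5359 in the knockdown course, 241 for the difference between arms and 109 genes opposing the course (686 before).

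Fits on the compared libraries alone, with less information on the spread, called 2 genes at day 0, 0 at day 1 (limma, 748 at an unadjusted p under 0.05) and 1725 at day 7. A minimum mean of 50 gave 41 genes at day 1. Weights per library gave 1 gene at day 1, 1390 at day 3, 2188 at day 5 and 2127 at day 7, and the cause was not tested. Without day 1 the mean of all days gave 3341 genes and 14 lists.

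Without 1 library, where the lone library of a group is assumed to vary like the other groups, counts ran from 100 to 530 genes at day 0, 18 to 743 at day 1, 74 to 296 at day 3, 459 to 974 at day 5, 286 to 553 at day 7, 283 to 929 for the difference between arms and 2077 to 3466 for the mean of all days. The lowest counts came without knockdown replicate 1 of days 0, 1 and 3, control replicate 1 of day 5 and knockdown replicate 2 of day 7, and the highest at day 1 without control replicate 2. In the control course no such fit moved a count by over 1.5 times.

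Of 22 lists 15 passed for the mean of all days with the preset correlation, 4 with an estimated one and 17 with fry, 13 after quantile scaling, and 13 to 16 without 1 library. Quantile scaling ended the calls of stress response (camera adjusted p = 0.0825) and immediate early genes (0.0873), and leaving out day 1 that of stress response genes (0.0717). The shift in position (-0.039, exact permutation p = 0.0463) became -0.0424 (exact permutation p = 0.0556) along the first principal component, and ran from -0.0353 to -0.0427 without 1 library.

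The replicate numbers gave no consistent pairing of the libraries. Deviations of same-numbered libraries correlated at -0.141, 0.178, 0.016, -0.017 and 0.041 between the arms at days 0, 1, 3, 5 and 7. For groups of different days these correlations ran from -0.109 to 0.106. The values of days 0 and 1 lay outside that range, so some shared structure within those days is not excluded. With the replicate block day 1 gave 12 genes, no other count moved by over 1.5 times, and the position shift stayed at -0.039 with an exact permutation p = 0.125.

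Depth limits what low genes can show, most of all in control replicate 2 of day 1 with about 12.0 M reads. With 2 libraries per group a change of 0.5 on the log2 scale was recovered at a single day in 42 to 47% of simulated genes. These were not low genes and had the same spread in all groups.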

Other observations

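The tests of hypoxia and antigen presentation genes were stated before their results but after the genes that prompted them were seen, and the test without Tap1 was chosen only after the result was seen.

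Class I antigen presentation genes were lower in the knockdown late in the course. H2-K1, which encodes a class I heavy chain and shares reads with related genes, stood at 18627 ± 1380 in the control and 7766 ± 898 in the knockdown at day 5, and at 15856 ± 720 and 7926 ± 420 at day 7. The light chain gene B2m stood at 37166 ± 888 and 24642 ± 808 at day 7 and the immunoproteasome gene Psmb8 at 2249 ± 217 and 868 ± 74.3. H2-Q6, also uncertain because of its near copies, was listed at 0 in the control at day 0 and stood at 1297 ± 207 and 359 ± 66.0 at day 7. B2m, Psmb8 and H2-Q6 are named here after their values were seen.

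H2-K1, Psmb9 and Nlrc5 prompted the hypothesis that antigen presentation genes are lower as a group. Of 16 other such genes 13 fell by limma at day 7, with a median of -0.65 and a camera p of 0.000636 with an estimated correlation (0.000682 to 0.00136 without 1 library), which is consistent with it. At day 5, 14 fell (median -0.76, a camera p of 0.000731) and at day 3, 7 fell (a camera p of 0.0108), while at days 0 and 1 limma called 0. The list holds Tap1, whose fall had been seen among p53 targets. Without it 12 of 15 fell at day 7 (a camera p of 0.000526; median -0.63), and the hypothesis was formed on the same libraries, so it remains one. Interferon-stimulated genes were lower at day 7 too, by camera with the preset correlation but not with an estimated one. Whether antigen presentation genes differ apart from interferon-stimulated ones was not tested.

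Slc16a3 and Egln3, which answer low oxygen, prompted the hypothesis that hypoxia-response genes are lower at day 7. Of 17 measured genes 5 fell and 1 rose by limma, with a median of -0.12 and a camera p of 0.0616 with an estimated correlation, which was 0.00262 without control replicate 2 and 0.12 without control replicate 1 of day 7. By the bound of 0.05 set beforehand this result counted against the hypothesis. A p this close to 0.05 that turns on 1 library decides little, so the hypothesis stays open for day 7. The list was not lower at day 3 (median 0.13, camera p = 0.311 with an estimated correlation). At day 5, where Slc16a3 was low too, 3 rose and 2 fell by limma (median 0.01, camera p = 0.87 with an estimated correlation). The list shares Pdk1, Slc2a1 and Pfkfb3 with glycolysis genes and Vegfa with secretory genes, so it may not be independent of those lists.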
